A study of Homo sapiens with 6 samples.

How the data were processed

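RNA from T24 cells, an established human bladder cancer line, was sequenced after transfection with a control small interfering RNA (siNC, 3 libraries) or one against USP43 (siUSP43, 3 libraries). Per the labels' protocols, total RNA was extracted with TRIzol and 2 μg per sample went into library construction, and the labels place all 6 samples in the same batch. Group and replicate number were taken from the sample titles. The labels do not say whether the numbers mark separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not say whether the 3 siUSP43 samples received the same duplex, and they give no duplex sequence.

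The deposited table holds raw read counts and FPKM (fragment counts scaled to exonic size and library total) for 63241 genes in each of the 6 samples, per the file headers. Reads were processed with cutadapt 2.6 and HISAT2 2.2.1 on genome build GRCh38, per the submitters' processing notes. The read counter, the annotation release, the strand setting and the treatment of multiply mapped reads were not given in the sources used here. The deposited FPKM values correspond to library totals 1.18 to 1.19 times the summed gene counts. Because strand use was not stated, a gene and an overlapping gene on the other strand cannot be told apart, and 40 of the 163 named genes overlapped another tested gene. Reads shared between near-identical copies, as for ribosomal protein genes, FTH1, keratins and histones, may have been divided between them.

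The fixed plan assumed that the table held FPKM alone and set limma on log2(FPKM + 1) as the test, with edgeR to be used if raw counts were present. Counts were present, so edgeR 4.0.16 in R 4.3.3 was the test used, with its quasi-likelihood fit and TMM scaling on the totals of all genes. Genes with a mean FPKM of at least 1 over the 6 samples were tested, and USP43 and E2F1 were kept whatever their level, which left 11417 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with group as the only term. Fold changes are siUSP43 over siNC. USP43 and E2F1 were also compared by an exact two-sided permutation test of 3 against 3 values, for which 0.1 is the smallest possible p.

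Before the data were examined, 35 gene lists were fixed, and the 31 with at least 5 tested members entered camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over the 31. The rule for named genes was fixed at the same time. It took USP43 and E2F1, the 12 largest increases and 12 largest decreases among changed protein-coding genes whose groups did not overlap and whose higher group had a mean FPKM of at least 2, up to 4 members of each list, and a fixed set of lipid, cell cycle and gemcitabine genes. Of that set, ABCG1 was below the filter and is not reported, and not every gene the rule selects is described.

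Total gene counts per library ran from 21430574 to 25577200, and the tested genes had a median of 895 counts per library. The exact interval for TTR and the floors cover counting error only, not the spread between libraries. That error may be understated, since the reads carry no molecular identifiers. Bootstrap intervals for ZNF genes resample genes and also leave out the spread between libraries. A count of 0 was given a floor of 3 counts.

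The scaling, pseudocount, filter, variance model, sample weights, replicate block and each left-out library were planned as alternatives. limma 3.58.1 on log2(FPKM + 1), the plan's test for a table without counts, became an alternative after the data were seen. The array weights and quantile normalization alternatives were also limma fits on log2(FPKM + 1), so their values include the effect of the added 1. DESeq2 1.42.0, RLE size factors, library totals alone, removal of a GC and exonic size trend, and removal of genes with seed-type sites were added after the data were seen. Sites were searched in GENCODE release 29 transcripts, to which 92.1% of identifiers matched.

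The tests were run on simulated counts for the 11417 genes of the siUSP43 and siNC comparison, in 20 draws with 200 genes changed by known folds. With dispersions that varied gene by gene, edgeR recovered 40.1% of genes changed 1.2-fold, 90.2% at 1.5-fold, 96.2% at 2-fold and 98.5% at 4-fold. False calls made up 7.87% of its calls on average (3.43 to 13.3% over the draws), above the 5% aimed at. With dispersions on the trend the average was 4.24%, and unadjusted p-values of unchanged genes lay under 0.05 in 5.02% and 5.09% of cases. The adjusted p-values may therefore be somewhat too small for genes whose dispersion lies far from the trend. Only 200 genes were changed in the simulation, while 56.1% of the tested genes passed in the data. The adjusted threshold was therefore stricter in the simulation, so the recovered and false shares need not carry over to the data. In the same draws a list of 30 changed genes ranked first in 20 of 20. Of 1000 random lists 0% had a camera p under 0.05, so camera was conservative on these simulated counts. That share need not carry over to the data. There the estimated correlation within the 6 lists that passed camera ran from -0.023 (NF-kB) to 0.102 (interferon response). Whether camera was conservative for lists with such correlations was not tested.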

Results

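The series asked how USP43, a deubiquitinating enzyme, bears on lipid metabolism in bladder cancer cells, and its title names cholesterol homeostasis, E2F1 and gemcitabine resistance. Gene expression was measured by RNA sequencing in T24 cells transfected with control (siNC) or USP43-directed (siUSP43) small interfering RNA, with 3 libraries in each group. The siNC libraries held 24049555, 24559697 and 24594508 gene counts and the siUSP43 libraries 25238301, 21430574 and 25577200. Mitochondrial genes took 5.41 to 5.81% of the counts.

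The groups stood apart on the first principal component of the log2 expression values, which held 76.0% of the variance. On log2(FPKM + 1), pairs of siNC libraries correlated at 0.9946 to 0.9956 across genes and pairs of siUSP43 libraries at 0.9909 to 0.9948, against 0.9633 to 0.9713 between groups. Genes are not independent replicates, so these values describe the libraries. No pair was as alike as counting noise alone would make it, since the chi-square per degree of freedom within groups ran from 2.13 to 11.3.

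USP43 (ENSG00000154914, GRCh38 chromosome 17, 9644698 to 9729687, plus strand) fell in the siUSP43 libraries, from 2.18 ± 0.159 to 0.830 ± 0.177 FPKM (SD, n = 3 each). Its log2 fold change was -1.40 with an SE of 0.14 (edgeR, Benjamini-Hochberg adjusted p = 5.63e-06), and the 3 siUSP43 values, at 1.02, 0.67 and 0.80 FPKM, all lay below the 3 siNC values. With limma on log2(FPKM + 1), where the added 1 is large beside these levels, the log2 fold change was -0.80. E2F1 (ENSG00000101412, chromosome 20, 33675477 to 33686385, minus strand), a transcription factor of the G1 to S transition, rose from 12.7 ± 0.289 to 17.98 ± 1.81 FPKM (SD, n = 3 each), a log2 fold change of 0.48 with an SE of 0.08 (edgeR, Benjamini-Hochberg adjusted p = 2.05e-04). These are mRNA levels, and protein was not analysed here. The exact two-sided permutation test gave p = 0.1 for each gene, the smallest that 3 against 3 allows.

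**Figure D1:**
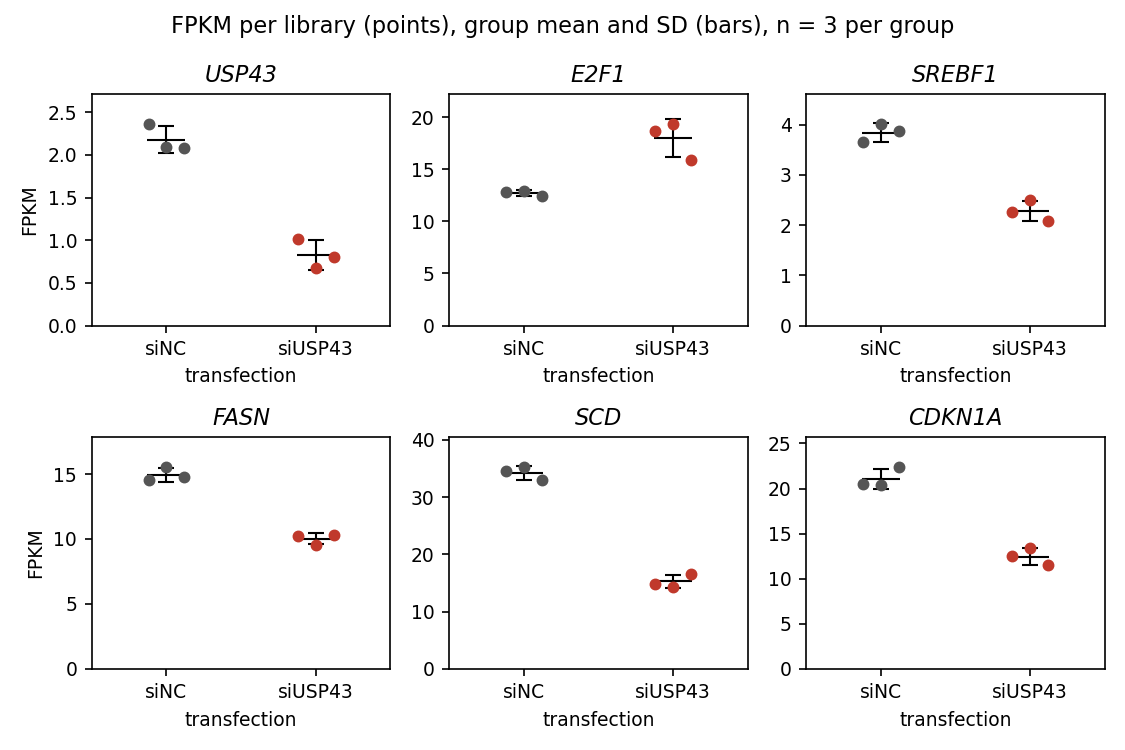
FPKM (vertical axes, from 0) of 6 genes in the 3 siNC and 3 siUSP43 libraries, with points for libraries and bars for the group mean and SD. USP43, SREBF1, FASN, SCD and CDKN1A were lower in all 3 siUSP43 libraries, and E2F1 was higher in all 3.

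Of the 11417 genes tested, 3198 rose and 3211 fell in siUSP43 (edgeR, Benjamini-Hochberg adjusted p under 0.05), and 5008 did not pass. Most changes were small, with a median absolute log2 fold change of 0.37 among genes that rose and 0.40 among those that fell, and 159 rose and 262 fell by a log2 fold change of at least 1. The groups did not overlap for 62.2% of tested genes, where chance gives 10%. The largest increase by the naming rule was in NPPB, the natriuretic peptide B gene (log2 fold change 2.89, SE 0.25), followed by ACTA2, smooth muscle actin (2.33, SE 0.11), and CDK14 (2.05, SE 0.08). NPPB and ACTA2 were below 1 FPKM in siNC, and limma on log2(FPKM + 1) gave 1.69 and 1.45, which would rank them below NOLC1 and TPM4. TAGLN, TPM4 and NEXN, which encode actin-binding or actin-associated proteins, had log2 fold changes of 1.78, 1.75 and 1.73. MESD, ZNF681, HABP4, NOLC1, TMEM40 and PODXL lay between 1.81 and 1.86, and NOLC1 went from 41.4 ± 0.934 to 147 ± 3.47 FPKM (SD, n = 3 each). ZNF681 and CDK14 were also below 1 FPKM in siNC. ZNF681 was at 1.2 with limma on log2(FPKM + 1), and CDK14 at 1.36 in such a fit with array weights.

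Among the largest decreases by the naming rule, which asks for a mean of at least 2 FPKM in the higher group, TTR, which encodes the thyroxine carrier transthyretin, had 413, 467 and 1030 counts in the siNC libraries and 0, 1 and 0 in siUSP43. The summed counts, scaled to library totals, were 1890 times higher in siNC (exact 95% counting interval 338 to 74500). MATN3, CD69, IL4I1, PKIA and CDKN1C followed with log2 fold changes of -2.58, -2.34, -2.29, -2.26 and -2.25. GCH1, ZDHHC20, AXL, CTSV, KRT81 and ALDH1A3 lay between -2.14 and -2.02. With limma on log2(FPKM + 1) the values of IL4I1, CTSV and KRT81 were -1.09, -1.30 and -1.06. AXL, a receptor tyrosine kinase, fell from 86.5 ± 2.34 to 20.8 ± 0.954 FPKM, and ALDH1A3, an aldehyde dehydrogenase, from 116 ± 4.81 to 28.99 ± 1.33 FPKM (SD, n = 3 each). Of these 12 genes, 6 carried the 7-mer GGATCCA or GATCCAA (a GGATCCA-type site) in the 3' UTR, as did CDK14 among those that rose, and of all 24 such named genes 18 fell. A seed match of a non-targeting duplex was carried there by 5 of the 12 genes with the largest increases. Most named genes were selected for their change and the 7-mers came from the same fold changes, so these counts are no separate support. Over all genes with a 3' UTR of at least 50 bases, GGATCCA-type sites were in 24.8% that fell at least 2-fold and 7.8% that rose so far. Among genes not past the test they were in 7.2%. For the non-targeting duplex the shares were 3.7%, 26.4% and 5.4%. ACTA2, CDK14, HABP4, IL4I1 and ALDH1A3 overlap other tested genes in the annotation and KRT81 has close paralogs, so the origin of their reads is uncertain.

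Cholesterol biosynthesis genes were not set apart from other genes by camera, while fry, which tests whether members move on balance in the same direction, gave a decrease (Benjamini-Hochberg adjusted p = 0.022). Of 20 tested members 2 rose, 9 fell and 9 did not pass, with 2 and 9 when adjusted over the list alone, a median log2 fold change of -0.06 and a camera Benjamini-Hochberg adjusted p = 0.733. HMGCS1, a synthase of the pathway, had a log2 fold change of -0.02 (SE 0.07) and did not pass. FDFT1 and DHCR7 fell, with log2 fold changes of -0.48 and -0.45, while PMVK and FDPS rose, with 0.78 and 0.39. SQLE had a log2 fold change of -0.16 (edgeR, Benjamini-Hochberg adjusted p = 0.0169), a call that ended in 6 of 22 alternatives. FDPS and DHCR7 here, and SREBF1, TMEM97, LPCAT3, LIPA, CPT2, G0S2 and ABHD5 below, overlap other tested genes, and their values are uncertain to that extent.

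Of 14 sterol sensing and uptake genes, 4 rose and 8 fell, the same counts when adjusted over the list alone, with a median log2 fold change of -0.27 and a camera Benjamini-Hochberg adjusted p = 0.217 (adjusted p = 0.0122 without a filter on low values). SREBF1, a master regulator of lipogenic genes, fell by 0.77 on the log2 scale (SE 0.08) and TMEM97, with 1 GGATCCA-type site in its 3' UTR, by 1.09 (SE 0.07). INSIG1 rose by 0.25 (SE 0.09; edgeR, Benjamini-Hochberg adjusted p = 0.0261), a call that ended in 5 of 21 alternatives. SREBF2 had a log2 fold change of -0.07 and did not pass. Of 8 cholesterol efflux genes 1 rose and 3 fell, the same when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.117, and adjusted p = 6.42e-04 without a filter). LPCAT3 fell by 0.33 (a call that ended without siNC replicate 2, and -0.20 under quantile normalization), NR1H2 rose by 0.31, and ABCA1 had a log2 fold change of -0.03. Of 14 storage and trafficking genes 4 rose and 2 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.984), among them NCEH1 at 0.94, LIPA at -0.78 and CAV1 at -1.04, the last with 2 such 3' UTR sites.

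Fatty acid synthesis genes included 3 that rose and 8 that fell of 22 tested, the same when adjusted over the list alone (median log2 fold change -0.04, camera Benjamini-Hochberg adjusted p = 0.217, and adjusted p = 0.0338 without a filter). SCD, the stearoyl-CoA desaturase gene, fell from 34.2 ± 1.17 to 15.3 ± 1.17 FPKM (SD, n = 3 each), a log2 fold change of -1.18 with an SE of 0.06. FASN had -0.59, HACD3 -0.89 and ACSL4 0.61. Of 24 glycerolipid and lipid droplet genes 5 rose and 14 fell, also when adjusted over the list alone (median -0.26, camera Benjamini-Hochberg adjusted p = 0.0856, passing in 4 of 22 alternatives), with G0S2, an inhibitor of triglyceride breakdown, at -1.38 and ABHD5, an activator of it that carries 1 GGATCCA-type site, at 0.74. Of 23 fatty acid oxidation genes 7 rose and 7 fell, the same when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.984), with CPT2 at 0.67 (0.43 with limma on log2(FPKM + 1)) and CPT1A at -0.64. Of 22 sphingolipid genes 9 rose and 7 fell, and 10 and 7 when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.939), with SMPD2 at -1.27 and UGCG at -0.63.

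E2F target genes of the G1 to S transition rose. Of 54 tested members 31 rose, 5 fell and 18 did not pass, with 33 and 5 when adjusted over the list alone, and the median log2 fold change was 0.18 (camera Benjamini-Hochberg adjusted p = 0.00212, and adjusted p = 0.0839 with an estimated correlation). PRIM1, MYBL2 and CDC25A rose, with log2 fold changes of 1.13, 0.84 and 0.82, while DTL fell by 1.22 on the log2 scale. CCNE1, the cyclin E1 gene, fell by 0.64 (SE 0.16; edgeR, Benjamini-Hochberg adjusted p = 0.00525). Of 41 G2 and M phase genes 26 rose and 6 fell, also when adjusted over the list alone, with a median of 0.25 (camera Benjamini-Hochberg adjusted p = 2.21e-04, and adjusted p = 0.0839 with an estimated correlation). MKI67, a proliferation marker, was at 0.50, HMMR at 1.04 and BIRC5 at 0.80. Of 21 genes of the E2F and RB family 8 rose and 7 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.79), with CDK6 at 0.94 and 1 GGATCCA-type site, TFDP1 at 0.76 and CCND1, the cyclin D1 gene, at -0.90. Of 35 DNA repair and fork genes 17 rose and 3 fell, the same when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.0856, passing in 8 of 22 alternatives), with TIPIN at 1.00 and BRCA1 at 0.50. Seed matches of the non-targeting duplex were also in the 3' UTRs of CDK6, MYBL2 and BIRC5 (1, 2 and 1), which rose, and of DTL (2), which fell. In other lists TNFAIP2, ATP5F1A and CPT1A, which fell, and H2BC5, which rose, each carried 1 such match. PRIM1, DTL, CCND1 and BRCA1 overlap other tested genes.

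Of 18 genes of gemcitabine transport and metabolism 5 rose and 4 fell, also when adjusted over the list alone, with a median log2 fold change of 0.01 (camera Benjamini-Hochberg adjusted p = 0.733). RRM1 and RRM2, the ribonucleotide reductase subunits, rose by 0.57 and 0.17, and SLC29A1, the equilibrative transporter, fell by 0.43 (SE 0.06). DCK, the activating kinase, had a log2 fold change of -0.15 (edgeR, Benjamini-Hochberg adjusted p = 0.0682) and CDA, the inactivating deaminase, one of -0.02. DCK passed in 3 of 22 alternatives. Of 6 ABC drug efflux genes 1 rose and 4 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.384), with ABCG2 at -0.91 and ABCB1 at -0.54 (-0.50 and -0.28 with limma on log2(FPKM + 1)) and ABCC3 at -0.49. Of 22 p53 target genes 5 rose and 10 fell, the same when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.384), CDKN1A, the p21 gene, at -0.78. Of 23 apoptosis genes 7 rose and 7 fell, and 7 and 8 when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.958), with CASP6 at -0.95 and CYCS, the cytochrome c gene, at 0.68. DCK, RRM2 and CASP6 overlap other tested genes.

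Glycolysis and hypoxia genes fell, 25 of 30 tested with 1 that rose, and 25 and 2 when adjusted over the list alone. The median log2 fold change was -0.47 (camera Benjamini-Hochberg adjusted p = 7.92e-12, and adjusted p = 0.0839 with an estimated correlation). VEGFA, NDRG1, PGK1 and LDHA had log2 fold changes of -1.23, -1.17, -1.08 and -0.84, and LDHA carried 1 GGATCCA-type site in its 3' UTR. NF-kB and cytokine genes fell, 17 of 25 with 2 that rose, and 18 and 2 when adjusted over the list alone (median -0.48, camera Benjamini-Hochberg adjusted p = 2.90e-08, and adjusted p = 0.0803 with an estimated correlation). TNFAIP2, CXCL8, CXCL1 and NFKBIA were at -1.80, -0.95, -0.76 and -0.59, and TNFAIP2, CXCL8 and CXCL1 each carried 1 such site. Interferon response genes fell, 15 of 22 with 0 that rose, also when adjusted over the list alone (median -0.53, camera Benjamini-Hochberg adjusted p = 3.34e-07, and adjusted p = 0.137 with an estimated correlation). OASL, IFIT1, IRF1 and IFIT3 were at -1.37, -1.06, -1.03 and -0.88, and LIPA overlaps IFIT1 and IFIT3 on the other strand. NRF2 and ferroptosis genes fell, 16 of 26 with 5 that rose, also when adjusted over the list alone (median -0.28, camera Benjamini-Hochberg adjusted p = 0.00101, and adjusted p = 0.0839 with an estimated correlation), with HMOX1 and FTH1 at -1.16 and -1.15. IRF1 and LDHA overlap other tested genes, and FTH1 has many near-identical copies. With an estimated correlation 0 of the 31 lists passed camera, and 6 had an unadjusted p under 0.05. The estimate lay below the preset 0.01 for the NF-kB (-0.023), NRF2 (-0.017), E2F target (-0.001) and G2 and M phase (0.008) lists. A higher correlation was therefore not what raised their p-values, and what did was not tested. By fry, which does not compare a list with other genes, 17 lists passed. Of these 17, 11 had not passed camera (fry Benjamini-Hochberg adjusted p = 9.69e-04 to 0.022). Among them fry gave decreases for 8 lists, cholesterol biosynthesis, sterol sensing, cholesterol efflux, fatty acid synthesis, glycerolipid, ABC efflux, p53 target and epithelial genes. It gave increases for 3, DNA repair, gemcitabine and unfolded protein response genes.

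**Figure D2:**
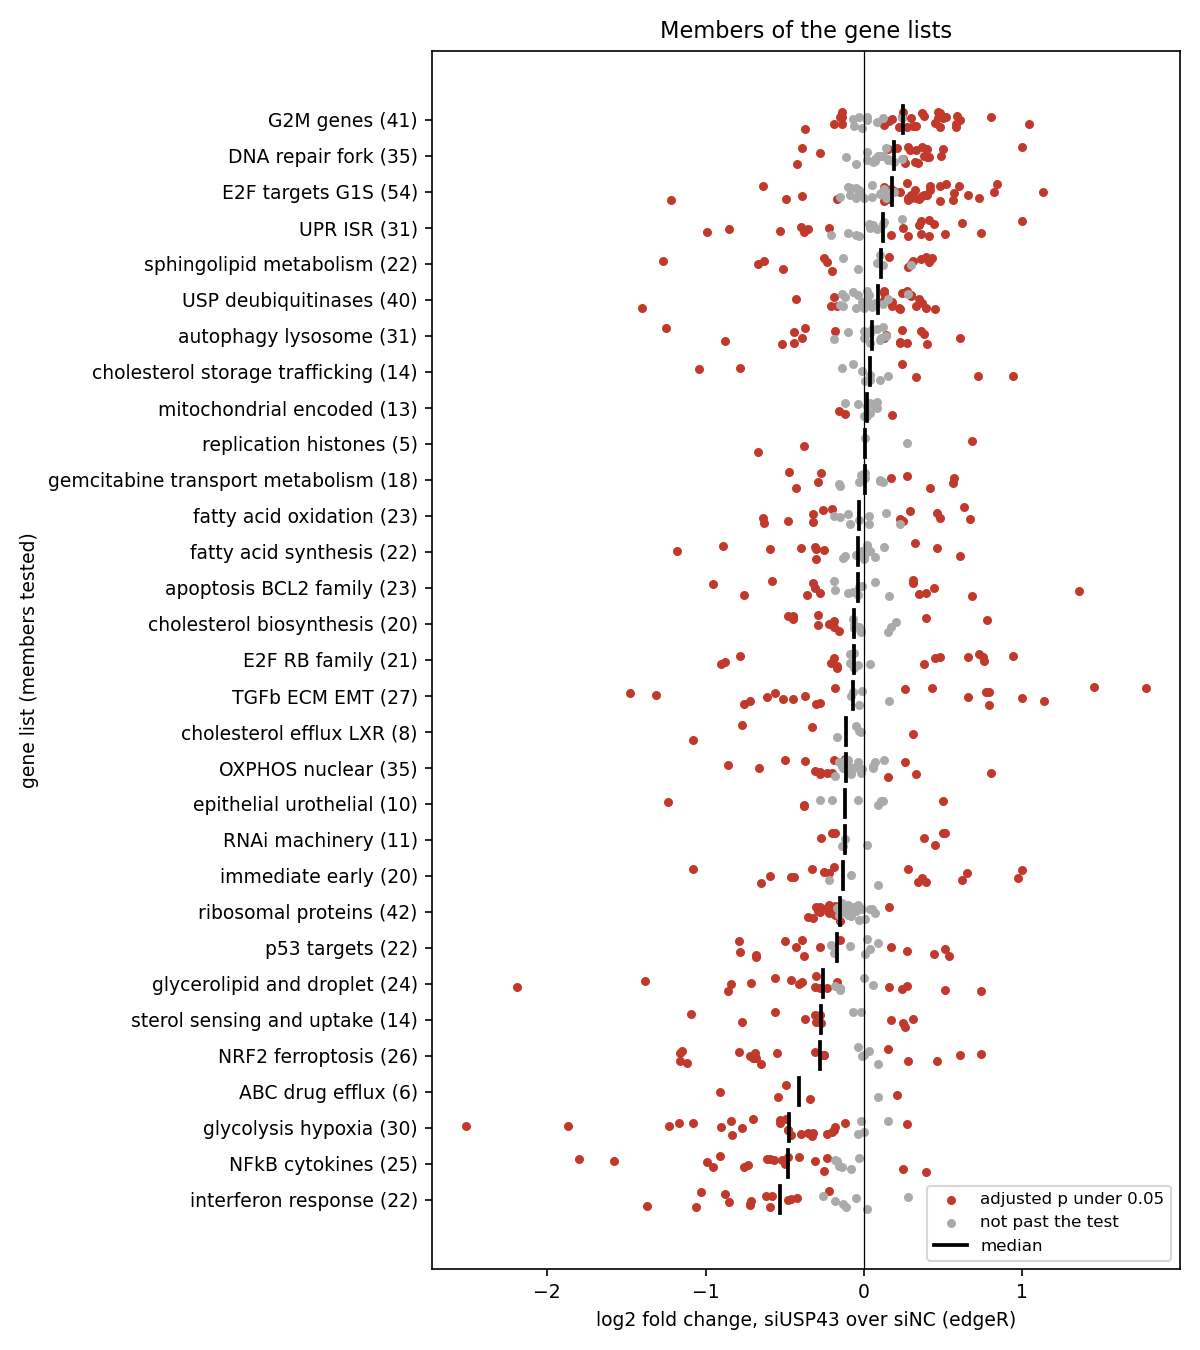
log2 fold change (siUSP43 over siNC, horizontal axis) of each tested member of the 31 gene lists (vertical axis, number of members in brackets), red where the edgeR adjusted p was under 0.05 and grey where not, with a black bar at the list median. The lowest medians were those of the interferon response (-0.53), NF-kB (-0.48) and glycolysis and hypoxia (-0.47) lists, and the highest that of the G2 and M phase list (0.25).

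The remaining lists did not pass camera with the settings used throughout. Of 42 ribosomal protein genes 1 rose and 19 fell, also when adjusted over the list alone (median -0.15, camera Benjamini-Hochberg adjusted p = 0.117, passing in 6 of 22 alternatives), RPL4 at -0.35 (-0.21 under quantile normalization). Of 35 nuclear OXPHOS genes 4 rose and 11 fell, and 4 and 10 when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.404), with ATP5F1A at -0.86 and UQCRQ at -0.66. Of 13 mitochondrially encoded genes 1 rose and 2 fell, and 1 and 1 when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.984), with MT-ND4 at -0.16, MT-ND1 at 0.18 and MT-CO2 at -0.12. The calls of MT-ND4 and MT-ND1 ended under quantile normalization (-0.04 and 0.06), and that of MT-CO2 ended in 7 of 22 alternatives. Of 31 unfolded protein and stress response genes 13 rose and 7 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.43), with ATF3 at 1.00 (0.66 with limma on log2(FPKM + 1)) and CEBPB at -0.99. Of 27 TGF-beta and matrix genes 10 rose and 12 fell, and 11 and 12 when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.958), with CCN2 and CCN1 at 1.45 and 1.14 and FN1 at -1.48. Of 20 immediate early genes 8 rose and 9 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.984), with EGR1 at 0.97 and FOSL1 at -1.08. Of 40 USP deubiquitinase genes 17 rose and 5 fell, the same when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.43), with USP32 at 0.45 and USP31 at 0.02. USP31, which carries 1 GGATCCA-type site in its 3' UTR, did not pass.

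Of 31 autophagy and lysosome genes 10 rose and 8 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.984), with BECN1 at 0.61 and NEU1 at -1.25. Of 11 RNA interference genes 4 rose and 3 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.79), with AGO4 at 0.50 and AGO2 at 0.38. Of 10 epithelial and urothelial genes 1 rose and 3 fell, the same when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.511), with FOXA1 at -1.24 and PPARG at 0.50. Of 5 replication histone genes 1 rose and 2 fell, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.984), H1-2 at -0.67. Markers of other cell types were nearly absent: 1 of 10 fibroblast markers was tested, ACTA2, and 0 of 8 endothelial and 0 of 10 blood markers. Of 8 liver and kidney epithelial markers 3 were tested and fell, TTR, SERPINA1 at -0.94 and PAX8 at -0.77, the latter pair at 14.1 and 38.4 FPKM in siUSP43. TTR and SERPINA1 each carry 1 GGATCCA-type site in the 3' UTR, and PAX8 carries 0. The median, the mean and the camera direction differed in sign for the cholesterol storage, sphingolipid, E2F and RB family, apoptosis, TGF-beta, immediate early, histone, autophagy and RNA interference lists, none of which passed camera.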

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

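The tests with DESeq2, RLE size factors, library totals alone, the GC and exonic size trend removed and seed-type site carriers left out were chosen after the results were seen, and limma on log2(FPKM + 1), planned as the test for a table without counts, was made an alternative then. Of 197 results, 165 kept their direction and their side of the threshold in every alternative that gave a value for them. The decrease of USP43 ran from -1.57 to -0.70 (highest adjusted p 0.000279), the increase of E2F1 from 0.43 to 0.66 (0.0025), and the median of the E2F target list from 0.17 to 0.21 (0.00749). The cholesterol biosynthesis list stayed between -0.14 and -0.03 and did not pass (adjusted p 0.406 to 0.869).

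The number of genes that rose and fell was 1889 and 1892 at a mean FPKM of at least 5, where fewer genes were tested, and 159 and 262 when an absolute log2 fold change of at least 1 was also required. They were 3839 and 4071 without a filter, 3883 and 3523 with array weights, 3406 and 2769 under TPM scaling and 3235 and 2917 with limma on log2(FPKM + 1). With 1 library left out it was 2718 to 3273 and 2710 to 3275. Of the calls still tested in each alternative fit, 84.3% to 99.6% were kept and 0 reversed. At a mean FPKM of at least 5, 3785 of the 6409 were tested and 3704 kept. A replicate block gave 2775 and 2841, and correlations of same-numbered libraries (-0.013, -0.126 and -0.261) gave no sign that the numbers pair. Without a filter 12 lists passed camera instead of 6, and the cause was not tested. Those gained were the sterol sensing, cholesterol efflux, fatty acid synthesis, glycerolipid, DNA repair and ribosomal lists, and the last 3 also passed in 3, 7 and 5 other alternatives.

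Reversals were seen in results that had not passed, and except where stated their cause was not tested. Under TPM scaling HMGCS1 was 0.015, ABCA1 0.007, CDA 0.015 and fatty acid oxidation 0.008. Under quantile normalization ABCA1 was 0.003, CDA 0.001, and MT-CO1 and the mitochondrial list 0. With array weights USP31 was -0.003, fatty acid oxidation 0.003, the gemcitabine list -0.024 and apoptosis 0.002. With the GC and exonic size trend removed CDA was 0.126, USP31 -0.048 and apoptosis 0.013. At a mean FPKM of at least 5 fatty acid oxidation was 0.02, ABC efflux 0.141, replication histones -0.675 and the epithelial list 0.018. There only 2 ABC efflux genes, 1 histone gene and 6 epithelial genes were left, so the loss of members accounts for those values. Without a filter the gemcitabine list was -0.01 and histones -0.201. With seed-type site carriers left out replication histones were -0.186 and RNA interference 0.018. With 1 library left out, some values crossed 0: MT-CO1 ran from -0.005 to 0.044, HMGCS1 from -0.086 to 0.038, ABCA1 from -0.157 to 0.043, CDA from -0.217 to 0.083 and USP31 from -0.015 to 0.04. The fatty acid oxidation list ran from -0.073 to 0.005, the gemcitabine list from -0.036 to 0.056, the mitochondrial list from -0.005 to 0.052 and the replication histones from -0.255 to 0.528.

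Thinning every library to the smallest total left 6319 to 6345 calls of 6409. In simulated data with this depth, sample number and spread, where 200 genes were changed, 40.1% of 1.2-fold changes were found. That share need not hold in the data, where 6409 genes passed. Which of depth, sample number and spread limits it was not tested.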

Other observations

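The gene ontology tests, the comparison with other splits of the samples, the test in genes without a seed match, the test of the non-targeting duplex, the ZNF medians by seed match and by number of coding 6-mers and both tests on TTR were chosen after the results were seen. Of 2092 gene ontology and pathway terms, 32 passed camera with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.934, and 88 with an unadjusted p under 0.05). Glycolytic process had 18 genes that fell and 3 that rose of 25 tested (median log2 fold change -0.32, camera Benjamini-Hochberg adjusted p = 0.000866), and response to hypoxia had 55 and 19 of 103. Response to type II interferon had 10 that fell and 1 that rose of 15, and extracellular matrix disassembly 11 and 2 of 18. Retinol metabolic process, a group that includes vitamin A converting enzymes, had 9 that fell and 3 that rose of 15 (median -0.46). Among terms that rose were structural constituent of muscle, with 9 up and 4 down of 15 (median 0.30), and spindle pole, with 60 up and 19 down of 110 (median 0.17).

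The first pattern was the number of genes past the test. The other 9 splits of the 6 samples gave at most 1 gene against 6409 for the real one (1 of 10 splits as large), and 10 splits are too few for a share under 0.05. Each of the other splits mixes siNC and siUSP43 libraries, so any difference between siNC and siUSP43 adds to the spread within its groups. That alone keeps their calls low, so their counts are no measure of what chance gives. Removal of the GC and exonic size trend kept 5711 of 6334 calls, and thinning every library to the smallest total, 21430574 counts, left at least 6319, which argues against those trends and depth as the whole cause. Genes with GGATCCA in the 3' UTR, a 7-mer that occurs in the USP43 coding sequence, were lower (z = -12.86, lowest of 15214 7-mers, against a lowest of -4.59 for the same 7-mers in 100 permutations of the fold changes over genes), so seed-type lowering by the siUSP43 duplex may account for part of the decreases. Of these 15214 7-mers, 3822 occur in a USP43 transcript, so that occurrence alone does not tie GGATCCA to the duplex, whose sequence is not given. Among genes without GATCCA in any annotated transcript 51.0% still passed, and 43.7% of the 2225 genes that also lack a seed match of the control duplex described next. These shares argue against direct lowering through GATCCA as the source of those calls. Seed matches of the other strand, or of another siUSP43 duplex, could not be searched for without a sequence. Direct lowering through such matches, loss of USP43, indirect effects of off-target genes and a difference between cultures stay open.

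The second pattern was a group of genes that were higher in siUSP43, among them 157 of 324 ZNF genes (35 fell, median log2 fold change 0.25), and the labels give no siRNA sequence. A non-targeting duplex in common use, known from general knowledge, has 4 seed-type 7-mers, and 3 of these exceeded the highest permuted z of 4.78 (TCGGAGA 6.08, CGGAGAA 6.06 and TGTCACG 4.91) while GTCACGA had 2.55, but 4 other 7-mers exceeded 4.78 too, 3 of them above every site of the duplex (highest GGAGAAA, 7.58), and these 3 hold GGAGAA, which the site CGGAGAA also holds. Release from lowering by a control duplex of this kind may therefore contribute to the changes of the 638 carriers, of which 283 rose and 143 fell (median 0.12), but whether this duplex was used is not given, and it was proposed from the same scan. The 108 ZNF genes without a 6-mer seed match of that duplex in any annotated transcript had a median of 0.26 (bootstrap 95% interval 0.19 to 0.34), against 0.23 for the 211 with a match, which argues against such matches as the cause of the rise in those 108. ZNF genes with a coding sequence were fitted on coding copies of GGAGAA, an incomplete match, and of GGAGAG, with coding length and GC. The slope on GGAGAA was 0.011 (bootstrap 95% interval -0.004 to 0.025), so no rise with its copies was shown in this model. That on GGAGAG was 0.042 (0.031 to 0.054), a difference in slope of -0.031 (-0.050 to -0.013). Without the model, medians were -0.07 with 0 copies and 0.28 with 3 or more of GGAGAA, and -0.01 and 0.40 of GGAGAG. The ZNF median was 0.23 after the GC and exonic size trend was removed. What raised these genes stays open, including the GGAGA that both 6-mers hold.

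The third pattern was the loss of TTR, from 1910 counts over the siNC libraries to 1 over the siUSP43 libraries. RNA from liver-type cells in siNC would bring albumin and apolipoprotein B, but ALB and APOB had 0 counts there, and the floor of 3 counts is 0.157% of the TTR counts. The lowest siNC library had 413, so no single library made the difference. TTR carries 1 GGATCCA-type site in its 3' UTR, though genes with the 8-mer GGATCCAA, the site class with the lowest median, had a median log2 fold change of -0.30, and direct lowering, a culture difference and an effect of USP43 stay open as untested causes.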
